A study of Homo sapiens with 15 samples.

How the data were processed

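The authors deposited gene counts for each library, and those counts were used here as given. Per the submitters' processing notes, reads were trimmed with fastp, aligned to GRCh38 with STAR and counted with featureCounts. Per the file headers of the IMR90 table, featureCounts was version 2.0.1 with GENCODE 38, and paired fragments were counted; the version and annotation behind the Huh7 table are not given in the sources used here. The Huh7 table held 59412 genes and the IMR90 table listed 59428 genes; 722 and 421 older symbols were replaced by current ones, and 38777 symbols were shared. Each sample was placed by its title and labels, and the meaning of the set number in the titles is not given. The descriptions of the Huh7 samples name a table under another name than the one used here. The description of 1 set 2 library (replicate 3) names Huh7, while its labels of line, tissue and treatment name IMR-90; it was kept in IMR90, and without it 8946 genes were called in the average.

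Each line was fitted on its own with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, after filterByExpr and TMM scaling, with p adjusted by Benjamini and Hochberg and called under 0.05. The 9 IMR90 libraries shared 1 fit, from which the average of the sets, each set and their difference were taken. The lines were compared in a joint fit of shared genes. The common biological coefficient of variation was 3.13% in IMR90, 8.20% in Huh7 and 5.49% in the joint fit. The groups, tests, gene lists, naming rule and alternatives, except that of leaving out the libraries labelled set 1, were fixed before the data were examined. Except in Fisher's exact tests, p-values measure only the spread between these samples. This spread may be technical, because the labels do not say that replicates were separate cultures. Fisher's exact tests count genes as independent units, which they are not, and hold no spread between samples. Floors of detection (3 counts) cover counting error only.

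The 26 gene lists, written from general knowledge, were tested with limma 3.58.1 camera on log2 CPM (prior count 2) at an inter-gene correlation of 0.01 and again with an estimated correlation; THBD was left out of them. Named genes were 8 fixed genes, the 6 largest rises and falls per comparison among called genes with a mean of at least 10 CPM in a group and replicates that did not overlap (in IMR90 called with the same sign in both sets), up to 2 members of each of 8 lists, and the 3 largest differences per direction between sets and between lines. Values of 3 genes that this rule named are not reported here. Alternatives were the scaling of DESeq2 1.42.0, upper-quartile scaling, the DESeq2 and voom tests, other filters, a replicate block and leaving out each library. Replicates of the same number did not correlate across groups (−0.0259 to 0.0225 in IMR90 and −0.0524 to −0.0158 in Huh7); no block had been planned for the main tests. Between replicates the chi-square per degree of freedom was 1.93 to 2.77 in IMR90 and 3.74 to 13.6 in Huh7, above the value of 1 for counting error alone.

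On counts with planted changes, the IMR90 average recovered 87.8% of 2-fold changes with 8 false calls, the libraries labelled set 1 85.3% with 5, the difference between sets 84.5% with 5, Huh7 76.0% with 9 and the joint fit 63.3% with 7. With a fall planted in the SASP cytokines, camera called that list in each comparison, and besides it 2 other lists in the average, 2 in the libraries labelled set 1, 4 between sets, 1 in Huh7 and 2 between lines; lists share members, and other genes were changed at random. Words of 7 bases were searched in GENCODE 29 3' UTRs of genes with at least 5 CPM in the control, with 100 shuffles per comparison; 163 IMR90 and 83 Huh7 genes were not searched. A planted word ranked first in 5 of 5 draws.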

Results

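RNA of cultured human cells was sequenced to ask whether THBD, the gene of the thrombin-binding membrane protein thrombomodulin, is needed when cells become senescent. IMR90, a lung fibroblast line, was studied during senescence that its treatment label ascribes to oncogenic HRAS. The growth protocol also describes replicative senescence of IMR90 by long passage, and the labels do not say whether that applies to these libraries. Huh7, a hepatocyte-derived carcinoma line, was studied during senescence induced by palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. In IMR90, 3 libraries carried a non-targeting short hairpin RNA (control) and 6 were labelled shTHBD, in sets of 3 that the sample titles number 1 and 2. In Huh7, 3 control libraries stood against 3 shTHBD libraries. Total gene counts ran from 1.83e+07 to 2.15e+07 per library in IMR90. They ran from 1.93e+07 to 2e+07 in the Huh7 control and from 2.25e+07 to 2.52e+07 in the Huh7 shTHBD libraries. Every comparison below is on counts as the authors deposited them, scaled here by library size (CPM). Values are means ± SD over n = 3 libraries per group, and log2 fold changes are given ± SE. This SE is approximate: the absolute log2 fold change over the square root of the F statistic of its test. For large changes from few counts it can fall below counting error alone, so it should not be read as their precision.

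THBD itself was measured first, since its level checks the labels. THBD lies on chromosome 20 from 23045633 to 23049672 (GRCh38), on the minus strand, in a single exon, and no other gene of the count table overlaps it. In IMR90 it stood at 18.6 ± 1.78 CPM in the control, 39.5 ± 1.51 CPM in the libraries labelled shTHBD set 1 and 10.6 ± 0.559 CPM in set 2. The counts behind these values were 315, 351 and 430 in the control, 719, 732 and 763 in set 1, and 199, 220 and 209 in set 2. THBD was therefore 2.12-fold above control in the libraries labelled set 1 (log2 fold change 1.09 ± 0.0764, adjusted p = 1.2e-20), against the direction of the label. It was 1.76-fold below control in set 2 (−0.81 ± 0.0905, adjusted p = 1.5e-12). The sets differed from each other by 1.90 ± 0.0831 (adjusted p = 2.5e-32). Their average did not pass the test (0.14 ± 0.0727, adjusted p = 0.102). In Huh7, THBD was near or below the floor of detection. The control libraries held 0, 0 and 6 counts and the shTHBD libraries 0, 0 and 0. A count of 0 allows up to 3 counts, or 0.119 to 0.133 CPM in the shTHBD libraries, so a fall of THBD in Huh7 was not detectable at this depth. Directions below are those of the labels; in the libraries labelled set 1, and in the average that includes them, they do not follow a fall of THBD. Nor can those in Huh7 be tied to a fall of THBD, which could not be measured there.

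**Figure D1:**
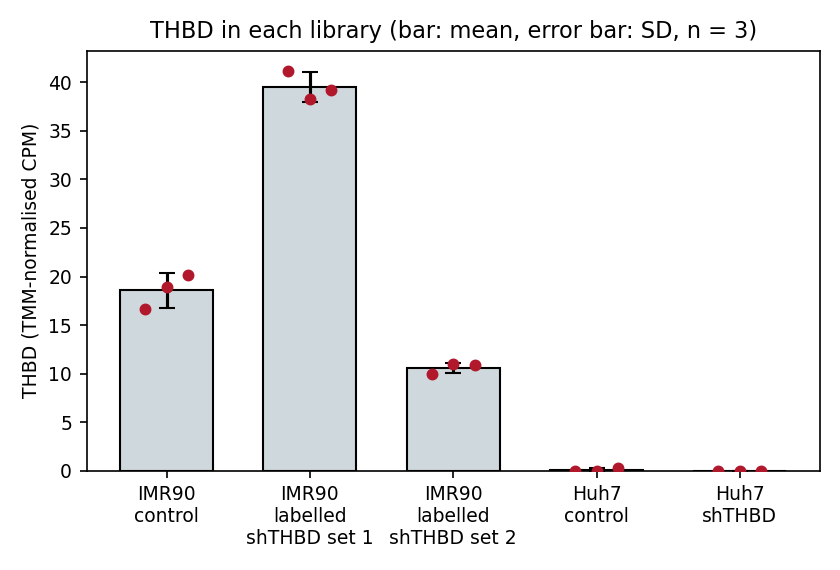
THBD in each library, in TMM-normalised CPM (points), with the mean (bar) and SD (error bar) of 3 libraries per group. The libraries labelled shTHBD set 1 lie above the IMR90 control and those of set 2 below it, and 5 of the 6 Huh7 libraries are at 0.

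The average of the 6 IMR90 libraries labelled shTHBD was compared with the 3 controls to ask how the senescent cells change when the hairpins are present. Secreted inflammatory genes fell. IL6, a cytokine of the senescence-associated secretory phenotype (SASP), went from 419 ± 4.28 CPM in the control to 248 ± 1.46 in the libraries labelled set 1 and 34.6 ± 2.18 in set 2. CXCL8, a neutrophil chemokine, went from 8770 ± 66.0 to 4647 ± 27.2 and 920 ± 21.9. On average IL6 fell by 2.18 ± 0.0263 and CXCL8 fell by 2.08 ± 0.0133 on the log2 scale (adjusted p = 1.2e-66 and 2.3e-84). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 1.69-fold (0.76 ± 0.0162, adjusted p = 5.8e-51) and CDKN2A, the p16 gene, 1.23-fold (0.30 ± 0.0358, adjusted p = 4.3e-11). CDKN2A was called in set 2 (0.54 ± 0.0403, adjusted p = 9.4e-20) and not in the libraries labelled set 1 (0.05 ± 0.0418, adjusted p = 0.28), and the sets differed (adjusted p = 1.3e-17). HRAS, the oncogene that the treatment label names, was 1.15-fold higher (0.21 ± 0.0201, adjusted p = 1.4e-14). F2R, the thrombin receptor PAR1, fell by 0.72 ± 0.0233 (adjusted p = 7.9e-40). LMNB1, whose loss marks senescent cells, was at 2.14 ± 0.555 CPM in the control and did not pass the test (0.11 ± 0.215, adjusted p = 0.698).

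Of 15411 genes tested in IMR90, 9067 differed between this average and the control, 4290 higher and 4777 lower, and 554 and 590 of these by at least 2-fold. The genes that rose most in both sets were CRYAB, a small heat shock protein (log2 fold change 4.42 ± 0.196), RAB7B, a GTPase of late endosomes (2.90 ± 0.174), RGS4, a regulator of G protein signalling (2.47 ± 0.0504), TRIML2 (2.46 ± 0.146), SLC2A14 (2.09 ± 0.186) and KRTAP2-3 (2.08 ± 0.134). SLC2A14 shares near-identical sequence with SLC2A3, and KRTAP2-3 with other keratin-associated protein genes, so their counts are uncertain. The largest falls were in MXRA5, an extracellular matrix protein gene (−2.95 ± 0.108), the chemokine gene CXCL6 (−2.73 ± 0.0703), COLEC10, a collectin (−2.68 ± 0.0991), TRPA1, an ion channel (−2.57 ± 0.0799), VWA5A (−2.36 ± 0.0731) and ABCG1, a cholesterol exporter (−2.27 ± 0.123). Adjusted p of these 12 genes was 3.5e-16 or lower. The average hides unequal sets for several of them: CRYAB rose by 6.66 in the libraries labelled set 1 and by 2.17 in set 2, and RGS4 by 0.35 and 4.60. With the 6 labelled libraries treated as 1 group, whose spread then includes the difference between sets, 2218 genes passed, and 3888 of the 9067 passed in each set with the same sign.

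Of 26 gene lists fixed beforehand, 9 moved against the other genes in this average (limma camera). SASP cytokines and chemokines fell. Of these, 20 of 26 tested members were lower and 3 higher, with 25 passing when adjusted over the list alone (median −1.30, adjusted p = 5.4e-15). Among them CXCL5 and CXCL1, neutrophil attractants, had log2 fold changes of −1.95 ± 0.0167 and −2.24 ± 0.023. SASP proteases, inhibitors and growth factors fell as a list (26 lower and 8 higher of 36, 34 adjusted over the list alone, adjusted p = 2.6e-09), among them IGFBP5 (−1.55 ± 0.0144). TIMP3, an inhibitor of metalloproteinases, rose 3.34-fold (1.74 ± 0.019). NF-kB targets were lower in 23 and higher in 5 of 32 (29 adjusted over the list alone, adjusted p = 1.2e-11), with CXCL3 at −2.10 ± 0.0233 and IL1B at −0.94 ± 0.0132. In the libraries labelled set 1 alone neither list was called: NF-kB targets were lower in 15 and higher in 14 (30 adjusted over the list alone, adjusted p = 0.477), and SASP proteases lower in 15 and higher in 17 (32 adjusted over the list alone, adjusted p = 0.718). CXCL1 and CXCL3 resemble each other closely, which may divide their counts. ER chaperones fell (20 of 23 lower and 2 higher, 22 adjusted over the list alone, adjusted p = 1.7e-11), including HYOU1 (−0.96 ± 0.0234) and HSPA5, the chaperone BiP (−0.62 ± 0.0162). Genes of the integrated stress response fell too (23 of 28 lower and 4 higher, 28 adjusted over the list alone, adjusted p = 6.7e-07), with CHAC1 at −1.73 ± 0.0583 and ATF4, the transcription factor of this response, at −0.66 ± 0.026.

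The p53 targets rose. Of 31, 26 were higher and 2 lower (28 adjusted over the list alone, median 0.50, adjusted p = 1.2e-11), among them CCNG1 (0.85 ± 0.0286). GDF15, a p53 target and stress cytokine, fell by 0.96 ± 0.0218. The cyclin-dependent kinase inhibitors rose (4 of 8 higher, 0 lower, 6 adjusted over the list alone, adjusted p = 0.00497), a call lost with adjusted p = 0.0541 with an estimated correlation. Interferon-stimulated genes fell (21 of 31 lower, 2 higher, 23 adjusted over the list alone, adjusted p = 0.00897; adjusted p = 0.0541 with an estimated correlation). Cholesterol synthesis genes fell as well (16 of 24 lower, 4 higher, 20 adjusted over the list alone, adjusted p = 0.0175; adjusted p = 0.0656 with an estimated correlation). In set 2 alone neither list was called: interferon-stimulated genes were lower in 16 and higher in 4 (19 adjusted over the list alone, adjusted p = 0.245), and cholesterol synthesis genes lower in 12 and higher in 9 (21 adjusted over the list alone, adjusted p = 0.451). The other 6 calls of the average held with an estimated correlation. Hypoxia and glycolysis genes did not pass as a list (11 higher and 16 lower of 30, 28 adjusted over the list alone, adjusted p = 0.0837), although SLC2A3, a glucose transporter, rose by 1.70 ± 0.023 and SLC16A3, a lactate exporter, fell by 1.38 ± 0.0205. Collagens and extracellular matrix genes went both ways (19 higher, 16 lower of 39, 36 adjusted over the list alone, adjusted p = 0.712), with COL6A1 and COL6A3, chains of collagen VI, at −0.98 ± 0.0142 and −0.81 ± 0.014.

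The remaining lists did not pass in this average. Their adjusted p was 0.0565 for antigen presentation by MHC class I, 0.0837 for oxidative phosphorylation, 0.134 for the lysosome, 0.148 for ERK pathway targets, 0.296 for mitosis and 0.56 for DNA replication. It was 0.654 for the list of thrombomodulin, protease-activated receptors and coagulation (THBD itself left out), 0.692 for NRF2 targets, 0.816 for TGF-beta targets and 0.849 for the BCL2 family and caspases. The medians and means of the last list and of TGF-beta targets differed in sign (−0.05 and 0.02 for the former, 0.02 and −0.05 for the latter). The lists of cell type markers did not pass either. Fibroblast markers, of the type of IMR90 itself, had adjusted p = 0.654. For other cell types it was 0.615 (hepatocyte genes), 0.781 (epithelial and cholangiocyte), 0.781 (leukocyte) and 0.177 (endothelial). The median and the mean of the fibroblast markers also differed in sign (−0.02 and 0.02). No leukocyte marker reached 10 CPM in an IMR90 group; the most abundant was CSF1R in the control (2.58 CPM) and LAPTM5 in the libraries labelled set 1 (8.78 CPM).

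The libraries labelled shTHBD set 1, in which THBD was above control, were then compared with the control alone. Hypoxia and glycolysis genes rose (21 of 30 higher, 7 lower, 28 adjusted over the list alone, median 0.34, adjusted p = 1.4e-06), with NDRG1, a hypoxia-induced gene, at 0.65 ± 0.0324 and SLC2A3 at 1.30 ± 0.0255. IL1B rose 1.54-fold (0.62 ± 0.0155, adjusted p = 1.4e-46) while IL6 and CXCL8 had log2 fold changes of −0.76 ± 0.0283 and −0.92 ± 0.016. MMP9, a gelatinase of the SASP, went from 11 ± 0.728 CPM to 159 ± 3.64. In all, 8297 of 15411 genes differed, 4213 higher and 4084 lower. In these libraries 13 lists were called, of which 9 held with an estimated correlation. SASP cytokines were lower in 14 and higher in 7 of 26 (21 adjusted over the list alone, adjusted p = 0.0362; adjusted p = 0.173 with an estimated correlation). ERK pathway targets rose (18 of 28 higher, 7 lower, 25 adjusted over the list alone, adjusted p = 9.9e-04; adjusted p = 0.0735 with an estimated correlation). NRF2 targets rose too (12 of 25 higher, 6 lower, 18 adjusted over the list alone, adjusted p = 0.026; adjusted p = 0.11 with an estimated correlation). Cyclin-dependent kinase inhibitors (4 of 8 higher, 4 adjusted over the list alone, adjusted p = 0.026; adjusted p = 0.0949 with an estimated correlation) and p53 targets (21 of 31 higher, 8 lower, 29 adjusted over the list alone, adjusted p = 1.0e-05) rose as in the average.

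In the same libraries labelled set 1, 7 further lists fell and held with an estimated correlation. Interferon-stimulated genes were lower in 21 and higher in 2 of 31 (26 adjusted over the list alone, adjusted p = 1.8e-04). The integrated stress response was lower in 20 and higher in 5 of 28 (25 adjusted over the list alone, adjusted p = 7.9e-06) and ER chaperones in 19 and 2 of 23 (21 adjusted over the list alone, adjusted p = 7.5e-09). Cholesterol synthesis genes were lower in 16 and higher in 3 of 24 (19 adjusted over the list alone, adjusted p = 2.5e-04). Collagens and extracellular matrix genes were lower in 22 and higher in 10 of 39 (32 adjusted over the list alone, adjusted p = 2.4e-05). Fibroblast markers were lower in 9 and higher in 2 of 14 (11 adjusted over the list alone, adjusted p = 2.5e-04) and lysosome genes in 18 and 6 of 34 (24 adjusted over the list alone, adjusted p = 0.0108).

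Set 2, in which THBD was below control, showed the largest falls of secreted factors in IMR90. SASP cytokines were lower in 22 and higher in 2 of 26 (24 adjusted over the list alone, median −2.59, adjusted p = 9.6e-15). IL6 fell 12.1-fold (−3.60 ± 0.036), CXCL8 9.54-fold (−3.25 ± 0.0175), CXCL1 17.3-fold (−4.11 ± 0.0321) and IL1B 5.67-fold (−2.50 ± 0.0166). NF-kB targets were lower in 28 and higher in 2 of 32 (30 adjusted over the list alone, median −1.02, adjusted p = 1.3e-15). Hypoxia and glycolysis genes were lower in 24 and higher in 3 of 30 (27 adjusted over the list alone, median −0.51, adjusted p = 6.4e-09), with SLC16A3 at −2.55 ± 0.0265 and NDRG1 at −2.49 ± 0.0418. FGF1, a fibroblast growth factor, went the other way, from 3.18 ± 0.392 to 77.9 ± 1.58 CPM. Here 10372 genes differed from control, 5123 higher and 5249 lower. Of the lists 12 were called, and 7 of these held with an estimated correlation.

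The other lists that fell in set 2 and held with an estimated correlation were SASP proteases and growth factors (30 lower, 5 higher of 36, 35 adjusted over the list alone, adjusted p = 1.6e-12), ER chaperones (21 and 2 of 23, 23 adjusted over the list alone, adjusted p = 2.1e-09) and the integrated stress response (19 and 6 of 28, 25 adjusted over the list alone, adjusted p = 7.4e-04). The p53 targets rose (26 higher, 3 lower of 31, 29 adjusted over the list alone, adjusted p = 1.8e-09). The call was lost with an estimated correlation for ERK pathway targets, which fell (18 lower, 7 higher of 28, 25 adjusted over the list alone, adjusted p = 4.6e-04; adjusted p = 0.0626 with an estimated correlation). It was lost for antigen presentation (12 lower, 3 higher of 18, 15 adjusted over the list alone, adjusted p = 0.0136; adjusted p = 0.142 with an estimated correlation). It was also lost for endothelial markers (6 lower of 9, 6 adjusted over the list alone, adjusted p = 0.00688; adjusted p = 0.0626 with an estimated correlation). Cyclin-dependent kinase inhibitors rose and lost the call (4 of 8, 4 adjusted over the list alone, adjusted p = 0.013; adjusted p = 0.0737 with an estimated correlation). Oxidative phosphorylation rose and lost it as well (22 higher, 6 lower of 35, 28 adjusted over the list alone, adjusted p = 0.0104; adjusted p = 0.304 with an estimated correlation). Mitochondrially encoded genes took 6.38% to 6.58% of counts in set 2, 5.82% to 5.98% in the libraries labelled set 1 and 5.43% to 5.48% in the control.

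The difference between the sets was tested directly. PI3, an elastase inhibitor, was at 58.4 ± 0.981 CPM in the libraries labelled set 1 and 0.66 ± 0.216 in set 2 (difference 6.46 ± 0.13), MMP9 at 159 ± 3.64 and 2.03 ± 0.486 (6.28 ± 0.0816), and LCE3D, a gene of the epidermal cornified envelope with close family members, at 10.5 ± 0.428 and 0.136 ± 0.0797 (6.22 ± 0.293). The growth factor genes EGF and FGF1 and the interferon-induced GTPase gene GBP2 were higher in set 2, with differences of −6.35 ± 0.26, −5.06 ± 0.106 and −4.89 ± 0.112. Adjusted p of these 6 genes was 1.8e-30 or lower. Between the sets 10709 of 15411 genes differed, 5228 higher and 5481 lower in the libraries labelled set 1. The lists called as higher in the libraries labelled set 1 were hypoxia and glycolysis (27 of 30 members higher, 29 adjusted over the list alone, median difference 0.87, adjusted p = 1.4e-14), NF-kB targets (28 of 32, 30 adjusted over the list alone, adjusted p = 1.4e-14) and SASP cytokines (20 of 26, 24 adjusted over the list alone, median difference 2.63, adjusted p = 6.4e-11). Also higher were ERK pathway targets (22 of 28, 23 adjusted over the list alone, adjusted p = 1.7e-08), SASP proteases (25 of 36, 36 adjusted over the list alone, adjusted p = 2.0e-07) and ER chaperones (17 of 23, 20 adjusted over the list alone, adjusted p = 0.00261). The p53 targets were lower there (24 of 31, 31 adjusted over the list alone, adjusted p = 1.5e-04).

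Another 5 of the 12 list calls between sets were lost with an estimated correlation. These were collagens and extracellular matrix (26 of 39 lower in the libraries labelled set 1, 37 adjusted over the list alone, adjusted p = 3.3e-04; adjusted p = 0.0538 with an estimated correlation) and oxidative phosphorylation (20 of 35 lower, 27 adjusted over the list alone, adjusted p = 0.0129; adjusted p = 0.31 with an estimated correlation). The others were fibroblast markers (9 of 14 lower, 13 adjusted over the list alone, adjusted p = 0.0161; adjusted p = 0.0778 with an estimated correlation), endothelial markers (6 of 9 higher, 7 adjusted over the list alone, adjusted p = 0.0222; adjusted p = 0.0926 with an estimated correlation) and DNA replication (19 of 37 higher, 22 adjusted over the list alone, adjusted p = 0.0421; adjusted p = 0.143 with an estimated correlation). Against the shared control, 3888 genes were called in both sets with the same sign, 1904 higher and 1984 lower, where independent lists would share 1401 and 1391. Another 2479 were called with opposite signs, where independent lists would share 2793. Genes such as F2R, TIMP3 and CDKN1A were among those changed alike, while IL1B and NDRG1 rose in the libraries labelled set 1 and fell in set 2. In 20 simulations of unchanged groups on shared controls, 0 genes were called in both. Unchanged groups give almost no calls by design, so this does not measure how far shared controls raise the overlap among changed genes. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.189 and their covariance 0.110, against a mean r of 0.498 and covariance of 0.0182 in the simulations. With 3 control libraries the controls could not be divided, so part of the excess may come from them.

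**Figure D2:**
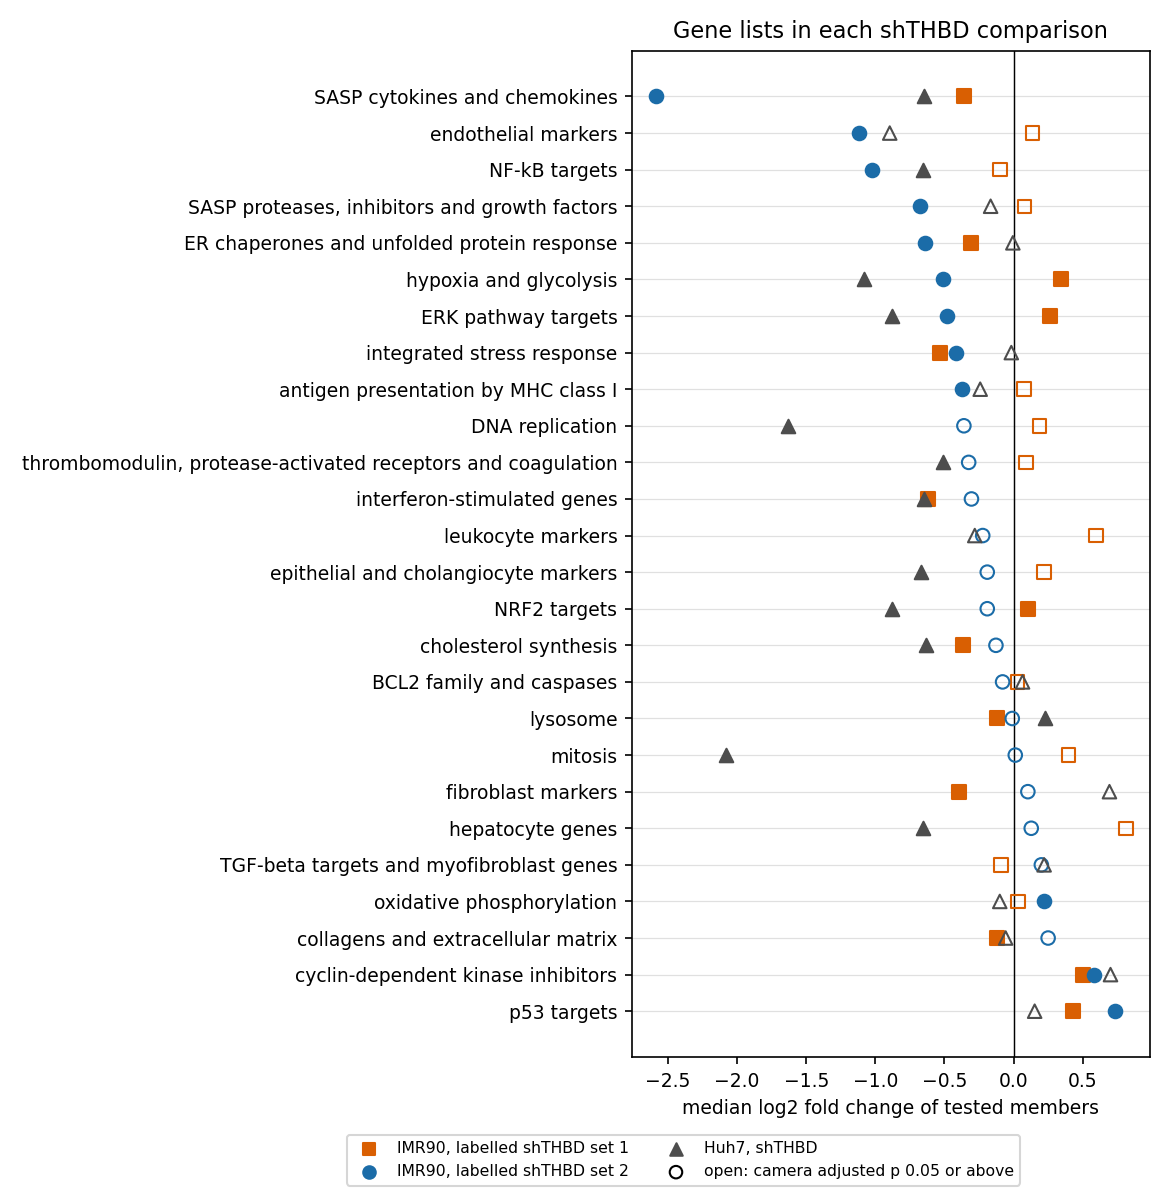
Median log2 fold change against control (horizontal axis) of the tested members of each of 26 gene lists, for the IMR90 libraries labelled shTHBD set 1 (squares), set 2 (circles) and Huh7 shTHBD (triangles); filled symbols passed camera and open ones did not. SASP cytokines lie furthest to the left in set 2 (−2.59), mitosis in Huh7 (−2.08), and hypoxia and glycolysis lies at 0.34 in the libraries labelled set 1 and −0.51 in set 2.

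In Huh7 cells made senescent with palbociclib, shTHBD was compared with control. Genes of cell division fell. In the list of DNA replication 39 of 40 members were lower and 0 higher (39 adjusted over the list alone, median −1.63, adjusted p = 1.1e-18). In that of mitosis 37 of 39 were lower and 1 higher (38 adjusted over the list alone, median −2.08, adjusted p = 1.3e-22). GINS4 and ORC6, which act at replication origins, went from 48.2 ± 1.2 to 7.39 ± 0.607 CPM (log2 fold change −2.71 ± 0.105) and from 47.3 ± 2.26 to 7.32 ± 0.645 CPM (−2.69 ± 0.106). MYBL2, a transcription factor of cycling cells, fell 7.05-fold (−2.82 ± 0.0714) and MAD2L1, of the spindle checkpoint, 4.71-fold (−2.24 ± 0.0953). LMNB1 went from 17.3 ± 0.5 to 13.5 ± 2.34 CPM (−0.36 ± 0.127, adjusted p = 0.017), a call lost without control replicate 1 (−0.35, adjusted p = 0.0568) or shTHBD replicate 3 (−0.24, adjusted p = 0.105). CDKN1A was low, at 7.22 ± 0.945 CPM in the control, and fell by 0.55 ± 0.189 (adjusted p = 0.0146), which did not hold without control replicate 1 (−0.44, adjusted p = 0.102) or shTHBD replicate 3 (−0.42, adjusted p = 0.06). CDKN2A (−0.02 ± 0.0891, adjusted p = 0.891), HRAS (−0.24 ± 0.122, adjusted p = 0.103) and IL6 (−0.27 ± 0.281, adjusted p = 0.439) did not pass the test. CXCL8 fell 3.65-fold (−1.87 ± 0.062) and F2R rose 2.17-fold (1.12 ± 0.0673).

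Of 17474 genes tested in Huh7, 9280 differed, 4518 higher and 4762 lower, and 921 and 1463 of these by at least 2-fold. The largest rises were in ASB2, a ubiquitin ligase subunit (3.62 ± 0.181), CATSPERG (3.46 ± 0.17), GLIPR1 (3.19 ± 0.0675), CYP26A1, which degrades retinoic acid (2.65 ± 0.19), UGT2B15, a glucuronosyltransferase (2.43 ± 0.0972), and CHI3L1, a secreted glycoprotein (2.31 ± 0.128). The largest falls were in SAA2, an acute-phase protein (−3.91 ± 0.161), CCL20, a chemokine (−3.84 ± 0.0728), ETV4, a transcription factor downstream of ERK (−3.83 ± 0.142), EME1 and RAD54L, of homologous recombination (−3.78 ± 0.194 and −3.76 ± 0.201), and SLC39A5, a zinc transporter (−3.73 ± 0.228). Adjusted p of these 12 genes was 1.1e-13 or lower. SAA2 is close in sequence to SAA1 and UGT2B15 to other UGT2B genes, which makes their counts uncertain. The shTHBD replicate 3 library stood apart from the other 5: its share of mitochondrially encoded counts was 9.94% against 7.26% to 8.35%. Without it 9189 genes were called.

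In Huh7, 13 of the 26 lists were called, 12 of them lower, and 10 held with an estimated correlation. NRF2 targets fell (24 of 26 lower, 0 higher, 25 adjusted over the list alone, median −0.88, adjusted p = 3.5e-15), with TXNRD1, thioredoxin reductase, from 1933 ± 87.1 to 305 ± 16.2 CPM and AKR1B10, an aldo-keto reductase with close relatives, from 499 ± 7.9 to 71 ± 1.94. Hypoxia and glycolysis genes fell (23 of 28 lower, 3 higher, 26 adjusted over the list alone, median −1.08, adjusted p = 6.1e-13), with NDRG1 at −2.52 ± 0.0564 and SLC16A3 at −2.41 ± 0.076. Cholesterol synthesis genes fell (22 of 25 lower, 2 higher, 24 adjusted over the list alone, adjusted p = 4.9e-09). Hepatocyte genes fell (33 of 45 lower, 6 higher, 40 adjusted over the list alone, adjusted p = 1.9e-08), including VTN (−1.95 ± 0.0535) and APOB, the main protein of VLDL (−2.03 ± 0.0639).

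ERK pathway targets (18 of 24 lower, 2 higher, 21 adjusted over the list alone, adjusted p = 4.2e-07) and NF-kB targets (17 of 28 lower, 2 higher, 20 adjusted over the list alone, adjusted p = 1.3e-06) also fell in Huh7. So did SASP cytokines (12 of 20 lower, 2 higher, 14 adjusted over the list alone, adjusted p = 1.9e-05) and interferon-stimulated genes (19 of 31 lower, 1 higher, 20 adjusted over the list alone, adjusted p = 1.9e-05). SASP proteases, inhibitors and growth factors were not called (10 lower, 10 higher of 26, 20 adjusted over the list alone, adjusted p = 0.421). Among the coagulation genes 20 of 27 were lower and 4 higher (24 adjusted over the list alone, adjusted p = 1.9e-05; adjusted p = 0.0512 with an estimated correlation), with SERPIND1, heparin cofactor, at −2.17 ± 0.0706. Epithelial markers fell (6 of 14 lower, 1 higher, 9 adjusted over the list alone, adjusted p = 0.00145; adjusted p = 0.0711 with an estimated correlation). Lysosome genes rose (19 of 34 higher, 8 lower, 27 adjusted over the list alone, adjusted p = 6.4e-04; adjusted p = 0.133 with an estimated correlation). Antigen presentation did not pass as a list (5 higher, 10 lower of 17, 16 adjusted over the list alone, adjusted p = 0.0628), although HLA-C and HLA-B, class I genes similar enough to share reads, had log2 fold changes of −3.72 ± 0.0784 and −2.24 ± 0.146. The p53 targets (10 higher, 8 lower of 29, 18 adjusted over the list alone, adjusted p = 0.412), ER chaperones (8 higher, 6 lower of 23, 15 adjusted over the list alone, adjusted p = 0.987) and the integrated stress response (9 higher, 11 lower of 28, 21 adjusted over the list alone, adjusted p = 0.989) did not pass. The ER chaperones had a median just below 0 (−0.00503) with a test directed up. CHAC1 rose 1.81-fold (0.86 ± 0.107).

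**Figure D3:**
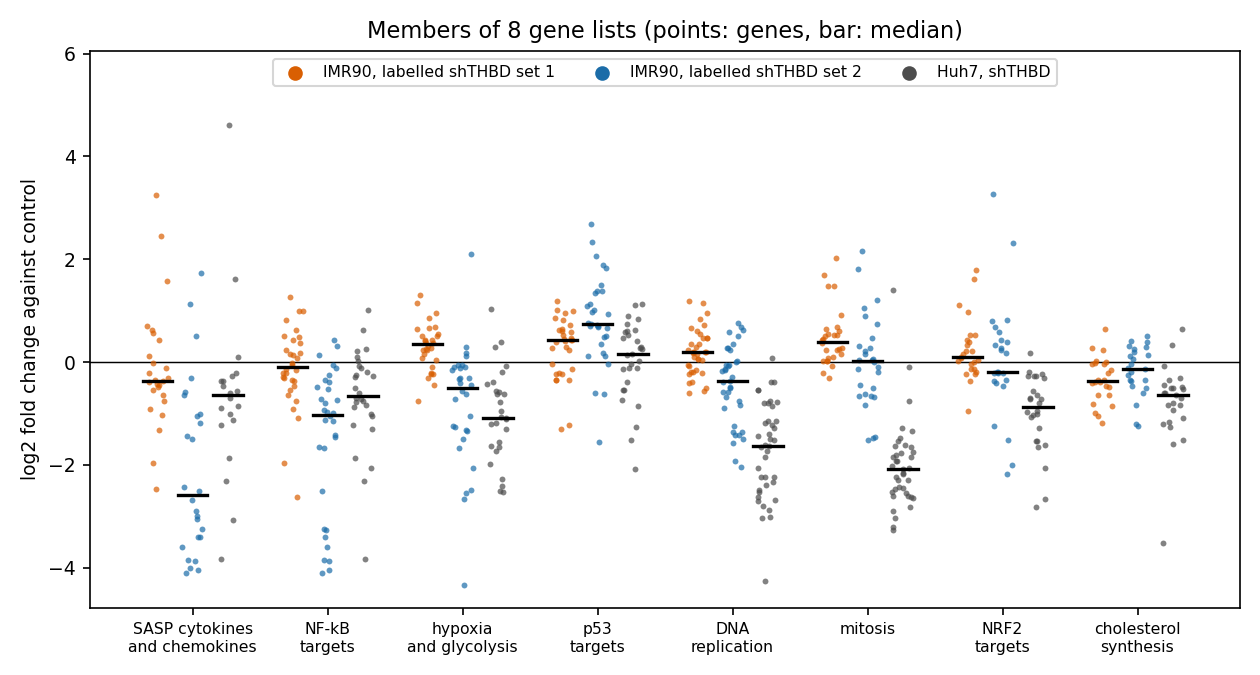
Log2 fold change against control of each tested member (points) of 8 gene lists, with the list median (bar), for the IMR90 libraries labelled shTHBD set 1, set 2 and Huh7 shTHBD. The medians of DNA replication (−1.63) and mitosis (−2.08) are far below 0 in Huh7, and that of SASP cytokines (−2.59) in set 2.

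Whether the response differed between the lines was tested in a joint fit of the 38777 genes named in both tables, as the IMR90 average minus the Huh7 change; the lines also differ in the labelled inducer of senescence and in count table. CRYAB rose in IMR90 and fell in Huh7, from 1.08 ± 0.217 to 0.211 ± 0.0987 CPM (difference 6.74 ± 0.444). The other 5 genes with the largest fitted differences had no counts in a control group, so only levels are given. IRAG2 and ELOVL2 were at 0 in the IMR90 control, with 0.303 ± 0.15 and 0.878 ± 0.147 CPM in set 2, and at 34.7 ± 3.86 and 21.4 ± 2.29 CPM in the Huh7 control. PDZRN3, FGF7 and BCL2A1 were at 0 in the Huh7 control and at 21.1 ± 0.0846, 45.1 ± 1.55 and 58.8 ± 1.82 CPM in the IMR90 control. DNA replication (36 of 40 members with a higher difference and 0 lower, 36 adjusted over the list alone, adjusted p = 4.6e-13) and mitosis (36 and 0 of 39, 37 adjusted over the list alone, adjusted p = 6.5e-14) fell in Huh7 and were not called in the IMR90 average. Their members named above were lower in the IMR90 control than in the Huh7 control. Whether this left less room to fall in IMR90 was not tested. GINS4, ORC6 and MAD2L1 did fall in the IMR90 average (−0.53 ± 0.141, −0.48 ± 0.136 and −0.49 ± 0.164, adjusted p = 0.0078 or lower). ORC6 rose in the libraries labelled set 1 (0.47 ± 0.143) and fell in set 2 (−1.43 ± 0.174). MYBL2 had 6 counts over the IMR90 control libraries and was too low to be tested in that average. GINS4, ORC6, MYBL2 and MAD2L1 were at 6.82, 6.09, 0.0961 and 4.37 CPM in the IMR90 control. In the Huh7 control they were at 48.2, 47.3, 186 and 52.7 CPM. In all, 7285 of 16871 genes tested differed, 3571 with a higher and 3714 with a lower value in IMR90.

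The calls of both lines overlapped. Of 12792 genes tested in each, 1750 were higher in both the IMR90 average and Huh7 and 2050 lower in both, where independent lists would share 1106 and 1299 (Fisher's exact test, two-sided, p = 7.5e-159 and 7.1e-200). These p-values count genes as independent, which they are not. Another 1471 had opposite signs. Genes lowered in both included CXCL8, CXCL1, CXCL3, CCL20 and CXCL6. The sets contributed unequally: set 2 and Huh7 shared 4480 calls with the same sign and 1403 with opposite signs, whereas the libraries labelled set 1 shared 2437 and 2282. Across genes, which are not independent replicates, Spearman's rho with Huh7 was 0.404 for set 2, −0.00769 for the libraries labelled set 1 and 0.309 for the average. CCL20 fell 16.4-fold in set 2 and 14.3-fold in Huh7 and stood at 127 ± 7.14 CPM in the libraries labelled set 1 against 128 ± 2.15 CPM in the control (adjusted p = 0.812). TXNRD1, NDRG1 and HLA-C fell in set 2 and in Huh7 and rose in the libraries labelled set 1, by 0.42 ± 0.0256, 0.65 ± 0.0324 and 0.34 ± 0.0267. The annotated 3' UTRs of THBD itself, TXNRD1, NDRG1, SLC16A3, TIMP3, COL6A1 and CHI3L1 hold both of the 6-base words GGCATC and GCAAGC that the closing section takes up. Those of CDKN1A, CRYAB, GINS4, ORC6, SERPIND1, HLA-C, HLA-B and FGF1 hold GGCATC, and those of CCL20, CXCL3, HYOU1, HSPA5, ABCG1 and ELOVL2 hold GCAAGC. Holding either word is common: 3561 of the 8732 genes searched in both lines do. The genes listed here went both ways in set 2, where TXNRD1 and NDRG1 fell while TIMP3 and CDKN1A rose, so this roll does not tie their changes to the words.

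**Figure D4:**
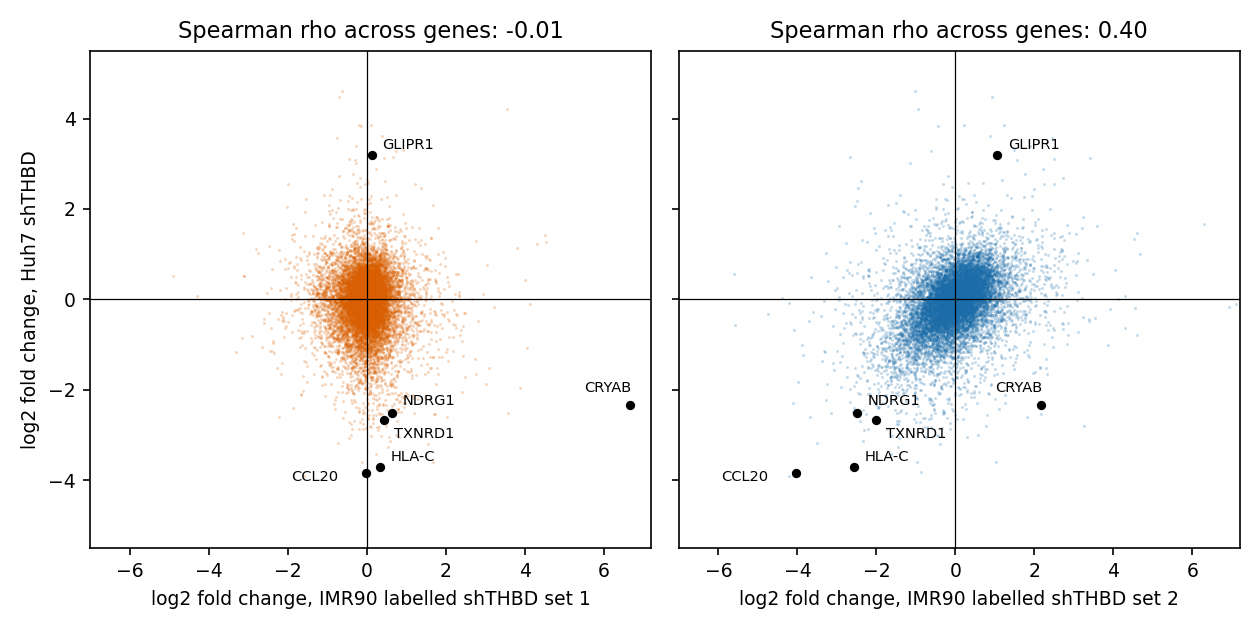
Log2 fold change in Huh7 shTHBD (vertical axis) against that in IMR90 (horizontal axis) for genes tested in both, with the libraries labelled shTHBD set 1 on the left and set 2 on the right; points are genes and 6 are named. Spearman's rho across genes was −0.00769 on the left and 0.404 on the right.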

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

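The medians over members with counts in every group were chosen only after the result was seen. Values here are differences in log2 fold change, the IMR90 average minus Huh7, and each is listed because its adjusted p was under the threshold between the lines. The lines also differed in the labelled inducer of senescence, count table and THBD level, and the average includes the libraries labelled set 1, in which THBD was above control. The count of genes that differed was 7285; of 25 joint regroupings of the libraries, 1 (the real one) reached it and the highest other gave 3508.

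Lists with a higher value in IMR90 had medians of 1.29 for DNA replication, 2.06 for mitosis, 0.62 for p53 targets, 0.74 for thrombomodulin, protease-activated receptors and coagulation, 0.58 for ERK pathway targets, 0.29 for cholesterol synthesis, 0.82 for hypoxia and glycolysis, 0.78 for NRF2 targets, 0.28 for oxidative phosphorylation, 1.16 for hepatocyte genes and 0.91 for epithelial and cholangiocyte markers. Lists with a lower value had medians of −0.49 for SASP proteases, −0.55 for the integrated stress response, −0.46 for ER chaperones and −0.39 for the lysosome. Over members with counts in every group the hepatocyte median was 0.68 (24 of 47 members). The named members of DNA replication and mitosis were lower in the IMR90 control than in the Huh7 control, as given above. The calls of coagulation (adjusted p = 0.0516 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.356 with an estimated correlation) were lost. Of the 25 regroupings 1 reached the 15 lists called, and the highest other gave 14.

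Among genes that rose in the IMR90 average or were named with it, the differences were CRYAB 6.74, RAB7B 2.31, RGS4 0.97, KRTAP2-3 2.35, SLC2A3 2.50, TIMP3 1.94, CDKN1A 1.28, CDKN2A 0.29, CCNG1 0.36 and HRAS 0.42. Among secreted factors and matrix genes they were IL6 −1.91, CXCL8 −0.24, CXCL3 −0.89, CXCL5 −1.60, CXCL6 −1.61, IL1B 3.83, CCL20 1.79, MXRA5 −2.68, COL6A1 −1.11, COLEC10 −2.59, GDF15 −0.85 and SERPIND1 1.70. For F2R, channels, transporters and stress genes they were F2R −1.87, TRPA1 −1.98, VWA5A −2.58, ABCG1 −3.17, CHAC1 −2.61, ATF4 −0.82, HYOU1 −0.50, HSPA5 −0.76, SLC16A3 1.01, NDRG1 1.58, TXNRD1 1.85 and AKR1B10 4.46.

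Among genes named for Huh7 they were ASB2 −3.01, CATSPERG −2.71, GLIPR1 −2.62, CHI3L1 −2.65, ETV4 3.34, EME1 2.78, RAD54L 4.07, GINS4 2.16, ORC6 2.19, MYBL2 4.73, MAD2L1 1.73, HLA-B 1.75 and HLA-C 2.59. Among genes named for the difference between sets they were EGF 1.71, FGF1 1.71 and GBP2 −0.86. CRYAB and TRPA1 were at 1.08 and 1.01 CPM in the Huh7 control and lower in Huh7 shTHBD, IL1B, MXRA5, ABCG1, KRTAP2-3, SLC2A3 and FGF1 were under 1 CPM in each Huh7 group, and MYBL2, EME1, RAD54L and CATSPERG were under 1 CPM in each IMR90 group, so their differences rest on few counts in that line.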

How the results depend on the processing

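No alternative reversed a result. The alternative that left out the libraries labelled set 1 was chosen only after THBD was seen above control in them. For the IMR90 average, 9067 genes became 2218 with the 6 labelled libraries as 1 group, 3888 when both sets had to pass with the same sign, and 10372 without the libraries labelled set 1; leaving out 1 library gave 8260 to 8946. With the replicate block the counts were 9010 for the average, 8237 for the libraries labelled set 1, 10317 for set 2, 10675 between sets, 8784 in Huh7 and 7092 between lines. Leaving out 1 library gave 7633 to 8429 genes for the libraries labelled set 1, 9932 to 10502 for set 2, 10346 to 10856 between sets, 8391 to 9189 in Huh7 and 6710 to 7301 between lines. The list calls fell from 12 to 7 in set 2 and from 12 to 7 between sets with an estimated correlation. The overlap of IMR90 and Huh7 ran from 3054 to 4480 over the alternatives, the highest being set 2 alone, and that of both sets from 3087 to 3901. Of single-gene results, 2405 stayed, 5 became weaker and 1 stronger; THBD in the IMR90 average passed without control replicate 3 (0.20, adjusted p = 0.0479), and the FGF7 difference between lines was lost without Huh7 shTHBD replicate 2 (−1.21, adjusted p = 1.0). Of single-list results, 2401 stayed, 29 became weaker and 40 stronger; SASP cytokines in the libraries labelled set 1 were lost with the filter of 1 CPM (adjusted p = 0.0545).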

Other observations

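The tests of scaling, exchanged labels, CD93, HRAS, the THBD level, core words, gene length, depth, lists without core-word genes and the overlap with Huh7 over IMR90 partitions were chosen only after the result was seen. The count of genes called in the IMR90 average was reached by 2 of 80 partitions of the 9 libraries, the real one (9067) and the one with the libraries labelled set 1 as control (9610). Of the 79 partitions other than the real one, 72 called 0. The same partitions gave as many lists as the real 9 in 39 of 80, the highest other 13, so the number of lists called is not distinguished from other groupings. The overlap of both sets (3888) was reached by 3 of 80, the highest other 6181 with set 2 as control, and the overlap with Huh7 as labelled (3800) by 1 of 80. The highest other overlap with Huh7, 3701, came with the libraries labelled set 1 as control, so it was nearly as large with those labels exchanged. For the libraries labelled set 1 (8297), set 2 (10372), the difference between sets (10709) and Huh7 (9280), 1 of 10 splits reached the real value and the highest other was 0. The Huh7 lists (13) were reached by 2 of 10, the highest other 13. With 10 splits these are too few for a share under 0.05.

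In the libraries labelled set 1, where THBD was above control, some genes picked after the data were seen were higher, and no list of heat shock genes was tested. HSPA1A, which encodes a heat shock protein, went from 20.6 ± 0.56 to 110 ± 2.16 CPM (2.42 ± 0.0554), HSPA6 from 1.45 ± 0.533 to 9.61 ± 0.946 CPM (2.70 ± 0.197) and DNAJB1 from 172 ± 0.629 to 299 ± 9.29 CPM (0.80 ± 0.0311). BAG3 and HSPH1, co-chaperones, rose by 0.85 ± 0.0323 and 0.71 ± 0.0267. TIE1, an endothelial receptor gene, went from 163 ± 2.73 to 358 ± 2.43 CPM there and to 95.7 ± 3.37 CPM in set 2. In set 2 and Huh7, NOP10, of small nucleolar ribonucleoproteins, had log2 fold changes of −2.30 ± 0.0497 and −2.90 ± 0.107, MDH2, malate dehydrogenase, −2.60 ± 0.0407 and −2.48 ± 0.0707, and NEDD8, a ubiquitin-like modifier, −2.21 ± 0.0894 and −2.88 ± 0.169. In the libraries labelled set 1 they were at 0.29 ± 0.0393, −0.20 ± 0.0333 and −0.10 ± 0.0725.

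THBD stood above control in the libraries labelled set 1. Scaling may be the cause, but the lowest log2 fold change over the scalings was 1.04, which argues against it. The labels of the libraries labelled set 1 and the control may have been exchanged. That THBD was 1.90 higher there than in set 2 follows from the order of the groups and decides nothing. Genes with the 3' UTR word AACGGGA were lower in the libraries labelled set 1 (z −7.21), which a hairpin in them could give. The control is labelled as carrying a non-targeting hairpin, so this could also arise with the labels exchanged. In set 2 the word had z −1.66, although its genes were called lower more often than others there too. The hairpin sequences are not given, so the exchange of labels stays open. Transcription of the locus may have risen, since CD93, which lies 29688 bases away (chromosome 20, 23079360 to 23086324), rose by 3.55 ± 0.161 in those libraries, which fits. In set 2 CD93 fell as THBD did, from 1.49 ± 0.421 to 0.773 ± 0.199 CPM (−0.96 ± 0.276, adjusted p = 0.0017), though at few counts. In Huh7 shTHBD, where THBD had no counts, CD93 was at 0.746 CPM against 0.0348 CPM in the control. TIE1, on chromosome 1 and picked after the data were seen, also moved as THBD did (1.13 ± 0.0298 in the libraries labelled set 1 and −0.77 ± 0.0332 in set 2). In all, 1393 of 15411 genes were called higher in the libraries labelled set 1 and lower in set 2, where independent lists would share 1435. A single gene that moved this way therefore does not tell whether the cause reached beyond the locus. Sequencing the hairpin inserts and measuring thrombomodulin protein in the same cells would separate these explanations.

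The Huh7 response resembled set 2 (rho 0.507 over 8732 searched genes) and not the libraries labelled set 1 (0.0453). A hairpin seed common to set 2 and Huh7 could act on other transcripts: the 3' UTR word with the strongest fall in Huh7, GGCATCA, ranked 1 in set 2 and 9005 in the libraries labelled set 1, which fits. The words in the compared genes may not be the whole cause, since rho was 0.455 across 5171 genes without either core word. Across 3561 genes with a core word rho was 0.555. Of 269 genes at least 2-fold lower in both, 72.5% held a core word, against 39.8% of all other genes. Among 39 genes at least 2-fold higher in both the share was 38.5%. These shares partly restate how the words were picked. A gene length trend (rho 0.525 with it removed) and a depth difference (rho 0.405 across all genes tested in both with the Huh7 libraries thinned to equal depth, 0.404 before) were argued against as the cause. Comparing the hairpin sequences with these words, and repeating with hairpins of other seeds or a hairpin-resistant THBD, would test it.

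Hypoxia and glycolysis genes and SASP cytokines differed between the sets. Lower HRAS in set 2 may contribute to that difference, since HRAS was lower there than in the libraries labelled set 1 by 0.0875 on the log2 scale (adjusted p = 5.6e-04). This difference in HRAS is small, so its part in the difference between the sets cannot be decided. HRAS was above control in both, by 0.16 ± 0.023 in set 2, where both lists fell below control. That argues against lower HRAS as the cause of those falls from control. Scaling may explain the difference between the sets. The highest adjusted p over the other scalings and voom was 1.3e-10. Camera compares a list with the other genes, so a shift common to all genes could hardly change it and this test cannot decide. The median difference over all genes was −0.0305 with TMM, −0.0173 with DESeq2 scaling and −0.130 with upper-quartile scaling. Those shifts are small beside the median differences of both lists given above, which argues against the choice of scaling as the cause. The hypoxia list may follow THBD, with a median of 0.34 in the libraries labelled set 1, where THBD was above control, whereas the SASP cytokines had −0.36 there, a call lost with an estimated correlation, so this cannot be decided. Titrating THBD with an inducible construct and measuring NDRG1 and IL6 would test it.

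Words of the seed search were as follows; GGCATCA was picked by its fall in Huh7 and AACGGGA by its fall in the libraries labelled set 1, so their values there restate that choice. Genes whose 3' UTR held GGCATCA were called lower in 61.1% against 41.1% of genes without it in set 2 (Fisher's exact p = 4.6e-32), in 53.6% against 34.8% in Huh7 (p = 4.1e-32) and in 33.6% against 32.5% in the libraries labelled set 1 (p = 0.490). In the libraries labelled set 1 the word with the strongest fall was AACGGGA (z −7.21, against a lowest z of −4.92 in the shuffles). Of 202 genes with it 107 were called lower there, against 32.2% of genes without it (Fisher's exact p = 1.9e-09). In set 2 it ranked 1172 with z −1.66, against a lowest z of −5.00 in the shuffles there. Of the 202 genes 107 were also called lower in set 2, against 42.9% of genes without it (Fisher's exact p = 0.00498). That share is not adjusted for 3' UTR length, base content or level, as z is, and the sets share controls. The word thus stood out in the search of the libraries labelled set 1 and not of set 2, while the share leaves its specificity unsettled. The words at ranks 2 and 4 in the libraries labelled set 1, ACGGGAG (z −5.77) and CGGGAGA (z −4.64, within the shuffles), occur in the coding sequence of THBD, at chromosome 20, 23049165 to 23049171 and 23049164 to 23049170; AACGGGA itself does not occur in the THBD transcript. THBD holds GCTTGCTCATAGGCATC, 17 bases at chromosome 20, 23047942 to 23047958, in its coding sequence, which includes GGCATC and the reverse complement of GCAAGC. Without genes that hold a core word, 3 of the 4 lists lowered in both stayed lowered: SASP cytokines (adjusted p = 3.6e-10 and 2.2e-04), NF-kB targets (3.7e-12 and 0.0014) and hypoxia and glycolysis (5.0e-05 and 4.1e-06), while ERK pathway targets did not in set 2 (0.211). The hairpin sequences are not given in the sources used here.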
